A study of Mus musculus with 19 samples.

How the data were processed

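The series holds RNA-seq of microglia-enriched brain homogenate from 19 mice in 4 groups, HEM and WT at 13 and 3 months of age. Per the labels' protocols, RNA was taken with an AllPrep column kit and libraries were made with NEBNext Ultra II RNA. Per the submitters' processing notes, Trimmomatic, HISAT2, featureCounts and DESeq2 and the mouse build mm10 were used, with no versions, roles, annotation, strand setting or filters given. The deposited values are a signal, gene counts that the authors had divided by 1 size factor per library. This was read from the values, of which 100% came out as whole multiples of the step of their library at a tolerance of 0.01. The steps equal the size factors DESeq2 computes from the recovered reads to a relative difference of 1.05e-10. The values cover 49671 genes, 8581 of them 0 in each library. Each of the 19 columns of the series-wide table equals exactly 1 library, in the matching group. File numbers run in another order than titles, so libraries are named here by group and by the number in the title, and groups come from the labels.

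Gene symbols, positions, lengths and GC content came from GENCODE M21 (mm10); 49326 of the IDs, 99.3%, had a symbol, and 99.6% of tested genes had a length and GC content. The genes tested had a value of at least 10 in at least 3 libraries, which left 23973. Recovered reads per library, the depth, give the totals in the results, and no library was left out.

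The test planned before the data were examined was edgeR's quasi-likelihood test on counts, with TMM factors. Since the files hold normalized values, limma-trend (limma 3.58.1, R 4.3.3, robust) on log2(value + 1) was used in its place. The 4 groups shared 1 model with no covariate, p-values were two-sided and Benjamini-Hochberg adjusted, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The comparisons, the 29 gene lists, the rule for named genes and the alternatives named first were also chosen before the data were examined. The comparisons were HEM against WT at each age, 13 against 3 months in each genotype, and the difference of the genotype effects.

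Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were also adjusted over the list alone. The mean log2 level of a list's tested members is its level in a library. Mouse Reactome pathways with 15 to 300 tested genes came from fgsea 1.28.0, through Entrez IDs held by 71.7% of tested genes. Of the genes in those pathways 96.2% matched.

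The named genes were Thy1, then per comparison the 8 called genes with the largest change in each direction among those with a mean log2 CPM of at least 1 and a symbol other than a predicted or clone name, and the 2 called members of each list with the smallest p. Where none was called, the 4 with the smallest p in each direction were named. Overlaps of age effects were set against independent lists, n1 × n2 / N, since the 2 comparisons share no library. Exons of 22 of the 110 named genes overlap those of another gene; over 50% of the exon bases are overlapped for Bloc1s1 and Tagln.

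Alternatives chosen in advance were edgeR 4.0.16 with RLE factors, DESeq2 1.42.0 and limma voom with quality weights on the recovered reads, no low filter, a filter at 50, the 2 compared groups alone, a covariate for neural material, the animal number as a block, the estimated correlation, and each library left out in turn. For the lists, TMM scaling stood in for RLE, since the deposited values already carry such factors. The planned edgeR test with TMM factors was run on the recovered reads as an alternative, on the genes tested here. Alternatives added after the data were seen were pseudocounts of 0.5 and 10, TMM scaling and a covariate for neutrophil and erythroid markers. Others added then were reads thinned to 60 M per library and the trend on gene length and GC content removed. The last left out 3 libraries that stand apart on principal components (HEM_13mo replicates 1 and 11, HEM_3mo replicate 3).

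The limma step was tested on simulated counts for 23467 genes. For HEM against WT at 13 months it called 31.3% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 92.4% of those changed 4-fold, with 7 false calls. For 3 months the shares were 20.9%, 59.7% and 95.5%, with 6 false calls. Of 28 random lists 0 were called, and the 1 changed list was. Simulated genes were drawn independently, while in the data the estimated correlation was 0.70 within oxidative phosphorylation and 0.91 within neutrophil genes. The simulated lists therefore say nothing about false calls at the preset correlation in the data. The changed genes were also drawn only from genes with more reads, so the shares called need not hold in the data. Replicate libraries were distinct, with log2 correlations from 0.942 to 0.981 and chi-square values per gene from 86.9 to 349. Marker lists for marrow granulocyte precursors, circulating neutrophils, osteoblasts and anterior pituitary were added after the data were seen; the first 2 bone and marrow lists lost Ibsp, Elane, Ctsg and Ms4a3 once their values were known, and both versions are reported. Correlations across libraries used 100000 permutations and were adjusted over 9 relations; 4 of these relations and 2 of the 110 named genes are not reported here. The paired methylation data were not part of these files.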

Results

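Total RNA was sequenced from microglia-enriched brain homogenate of 19 mice. The HEM mice carried a human transgene driven by the Thy-1 promoter and inserted on the X chromosome. The WT mice were controls, and the background was B6D2F1/J. There were 8 HEM and 4 WT mice at 13 months of age, and 4 HEM and 3 WT mice at 3 months. Depth was 63.3 to 95.8 M reads in genes per library for HEM at 13 months (mean 75.3 ± 13.0 M, SD, n = 8) and 93.2 to 124.5 M for WT at 13 months (110.7 ± 14.9, n = 4). At 3 months it was 74.7 to 112.9 M for HEM (92.4 ± 16.4, n = 4) and 83.0 to 106.8 M for WT (92.9 ± 12.4, n = 3). Below, each gene's change is a log2 fold change with its standard error, each adjusted p of a gene is from limma-trend with Benjamini-Hochberg adjustment over 23973 tested genes, and each list result is from limma's camera over 29 lists.

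The gene of the promoter was looked at first. Thy1 (ENSMUSG00000032011, mm10 chromosome 9, 44043384 to 44048579), a neuronal and T cell surface glycoprotein whose promoter drives the transgene, averaged 11922 ± 11012 normalized counts in HEM and 4404 ± 2418 in WT at 13 months (SD, n = 8 and 4). At 3 months the averages were 27558 ± 15954 and 7429.5 ± 3796 (SD, n = 4 and 3). All 4 HEM libraries at 3 months, from 18307 to 51370, lay above the 3 WT libraries, from 3367 to 10886. The groups did not overlap at that age for 5.86% of all tested genes, where chance gives 5.71%. The differences of 1.20 ± 0.49 at 13 months and 1.90 ± 0.62 at 3 months had limma adjusted p of 0.127 and 1.0, while DESeq2 called Thy1 at 13 months (adjusted p = 0.0294). Neuron genes as a list had medians of 0.16 at 13 months and 1.10 at 3 months, and T and NK cell genes 1.25 and 0.65, with the tests given below. With age Thy1 differed by -0.74 ± 0.62 in WT (adjusted p = 0.619) and by -1.44 ± 0.49 in HEM (adjusted p = 0.144, or adjusted p = 0.0287 without HEM_13mo replicate 3).

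**Figure D1:**
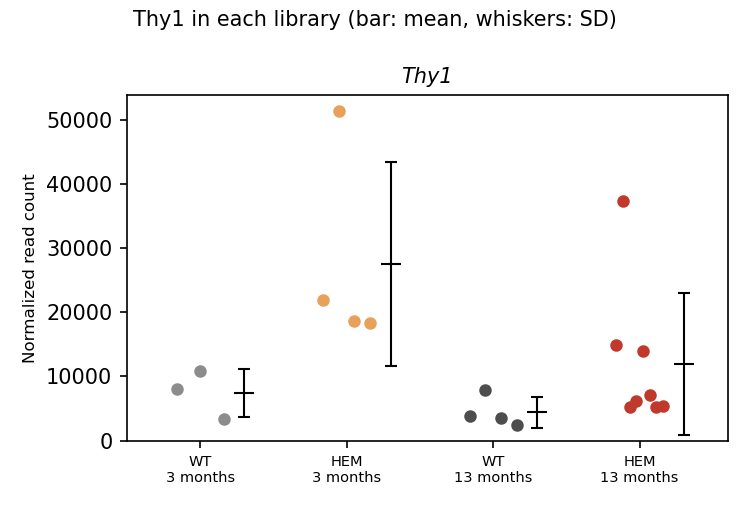
Normalized read counts of Thy1 in each library, by genotype and age; each point is 1 mouse, the bar is the group mean and the whiskers are the SD. At 3 months the HEM and WT libraries did not overlap, which chance gives for 5.71% of genes.

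The 13-month comparison asked how the transgene altered transcripts of this preparation in older mice. HEM mice had less transcript of the mitochondrial respiratory chain and of choroid plexus genes than WT mice, and more of immediate early, inflammatory, cell cycle and neutrophil genes. Each of these 6 lists lost its call with an estimated correlation (adjusted p = 0.197), and the cell cycle median fell from 1.60 to 0.24 with the neutrophil and erythroid marker level in the model. Ndufa1 (mm10 chromosome X, 37187588 to 37191163), a subunit of respiratory complex I, averaged 4634 ± 559 normalized counts in HEM and 9054 ± 1227 in WT (SD, n = 8 and 4), a log2 change of -0.97 ± 0.10 with adjusted p = 0.000554. Elane (mm10 chromosome 10, 79886247 to 79888215), the neutrophil elastase made by granulocyte precursors, rose from 431 ± 183 in WT to 7016 ± 5942 in HEM (3.57 ± 0.75, adjusted p = 0.00523). In all, 2918 genes changed, 1167 higher and 1751 lower in HEM. At least 2-fold changes were mostly rises, 615 against 143 falls. At an unadjusted p under 0.05 there were 5965 genes, where chance gives 1199. Over all tested genes the 8 HEM and 4 WT libraries did not overlap for 6.66%, which chance gives for 0.404%.

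All 34 oxidative phosphorylation genes, which encode the electron transport chain and its terminal oxidase, fell in HEM. Oxidative phosphorylation genes had a median of -0.53 (adjusted p = 5.13e-32, or adjusted p = 0.197 with an estimated correlation), with 34 lower adjusted over the list alone. Their mean level was 13.08 ± 0.15 in HEM and 13.64 ± 0.21 in WT (log2 scale, SD, n = 8 and 4), against 13.15 ± 0.014 and 13.12 ± 0.13 in HEM and WT at 3 months (SD, n = 4 and 3), so WT at 13 months stood apart. Besides Ndufa1, the succinate dehydrogenase subunit Sdha fell (-0.52 ± 0.08, adjusted p = 0.00176). Of 27 lysosome and autophagy genes 6 fell, including Atp6v1a, a subunit of the proton pump that acidifies lysosomes (-0.64 ± 0.13, adjusted p = 0.00383), and Smpd1, which encodes acid sphingomyelinase (-0.47 ± 0.09, adjusted p = 0.0040). Lysosome genes had a median of -0.13 (adjusted p = 0.000612, or adjusted p = 0.298 with an estimated correlation), with 1 higher and 7 lower adjusted over the list alone. Park7 (-0.50 ± 0.09, adjusted p = 0.00255), an oxidative stress sensor, and Pink1 (-0.45 ± 0.11, adjusted p = 0.0121), a kinase that marks damaged mitochondria, fell among 20 tested Parkinson disease genes. The share of 2 in 20 is near that over all tested genes, 2918 of 23973. Parkinson disease genes had a median of -0.01 (adjusted p = 0.982, or adjusted p = 0.993 with an estimated correlation), with 2 lower adjusted over the list alone. Of 12 ependyma and choroid plexus genes 8 fell. Choroid plexus genes had a median of -0.90 (adjusted p = 1.3e-05, or adjusted p = 0.197 with an estimated correlation), with 9 lower adjusted over the list alone. The 8 included Ttr, the thyroid hormone carrier secreted by the choroid plexus (-0.93 ± 0.21, adjusted p = 0.0065), and the forebrain and choroid plexus regulator Otx2 (-1.12 ± 0.20, adjusted p = 0.00272).

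Of 20 immediate early and dissociation stress genes, which respond within minutes to stimulation or tissue handling, 18 rose in HEM. Immediate early genes had a median of 1.59 (adjusted p = 1.98e-16, or adjusted p = 0.197 with an estimated correlation), with 18 higher adjusted over the list alone. Fosb, an AP-1 subunit, was measured at 41306 ± 17936 in HEM and 7583 ± 8212 in WT (3.25 ± 0.58, adjusted p = 0.00247), with Atf3 at 2.97 ± 0.50 and Egr2 at 2.95 ± 0.42. The list's level was 14.17 ± 0.52 in HEM at 13 months and 12.53 ± 0.80 in WT, against 14.62 ± 0.20 and 14.43 ± 0.61 in HEM and WT at 3 months (SD, n = 8, 4, 4 and 3). Of 24 inflammatory cytokine and NF-kB genes 13 rose, including the chemokine Ccl4 (2.27 ± 0.38, adjusted p = 0.00213) and the anti-inflammatory cytokine Il10 (3.83 ± 0.59, adjusted p = 0.00176). Inflammatory genes had a median of 1.39 (adjusted p = 6.04e-13, or adjusted p = 0.197 with an estimated correlation), with 15 higher adjusted over the list alone. Their level was 10.84 ± 0.36 in HEM and 9.50 ± 0.38 in WT at 13 months (SD, n = 8 and 4). At 3 months it was 11.01 ± 0.46 in HEM and 10.59 ± 0.27 in WT (SD, n = 4 and 3). For this list and the immediate early list, WT at 13 months was thus the low group that stood apart. Of 24 interferon response genes 6 rose, among them the nucleic acid sensor Zbp1 (1.18 ± 0.29) and Slfn2 (0.99 ± 0.21). Interferon response genes had a median of 0.52 (adjusted p = 1.02e-06, or adjusted p = 0.33 with an estimated correlation), with 10 higher adjusted over the list alone. With the neutrophil and erythroid marker level in the model the interferon median was 0.20. Of 18 antigen presentation genes 5 rose. Antigen presentation genes had a median of 0.45 (adjusted p = 3.9e-05, or adjusted p = 0.298 with an estimated correlation), with 11 higher adjusted over the list alone. The 5 included the MHC class II chains H2-Aa (0.67 ± 0.14, adjusted p = 0.00542) and H2-Ab1 (0.62 ± 0.15, adjusted p = 0.0089), which belong to a family of similar genes between which reads could be divided. The central complement component C3 was the 1 riser of 22 pattern recognition, complement and Fc receptor genes (1.90 ± 0.40, adjusted p = 0.00508), but its change was 0.22 (adjusted p = 0.946) with that marker level in the model. Pattern recognition genes had a median of 0.32 (adjusted p = 0.00148, or adjusted p = 0.406 with an estimated correlation), with 1 higher adjusted over the list alone.

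Few microglia markers passed the test, at shares near or below that of all tested genes, 2918 of 23973. These counts therefore do not set microglia genes apart. Of 18 homeostatic microglia genes 2 fell, the fructose transporter Slc2a5 (-1.03 ± 0.33, adjusted p = 0.0488) and the matrix protein Sparc (-0.40 ± 0.13, adjusted p = 0.044), whose calls were lost in 14 and 12 of the 19 fits that left out 1 library. Homeostatic microglia genes had a median of -0.18 (adjusted p = 0.15, or adjusted p = 0.959 with an estimated correlation), with 0 called adjusted over the list alone. Of 15 pan-microglia and myeloid genes 1 rose, the leukocyte phosphatase Ptprc (0.70 ± 0.15, adjusted p = 0.00497). Pan-microglia genes had a median of -0.13 (adjusted p = 0.93, or adjusted p = 0.993 with an estimated correlation), with 1 higher adjusted over the list alone. Of 23 tested disease-associated microglia genes 2 fell, the tetraspanin Cd63 (-0.43 ± 0.10) and the metalloproteinase inhibitor Timp2 (-0.42 ± 0.12). Disease-associated microglia genes had a median of -0.07 (adjusted p = 0.982, or adjusted p = 0.993 with an estimated correlation), with 5 higher and 5 lower adjusted over the list alone. Of 12 border-associated macrophage genes 1 rose, Ms4a6b (0.67 ± 0.20, adjusted p = 0.0343), a call lost in 7 of those 19 fits, and its change was 0.056 with the animal number as a block. Border-associated macrophage genes had a median of -0.12 (adjusted p = 0.982, or adjusted p = 0.993 with an estimated correlation), with 1 higher adjusted over the list alone.

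Most neutrophil and cell cycle genes rose, with some genes of other blood cells. Of 12 neutrophil genes 11 rose, with the antimicrobial peptide Camp at 2.42 ± 0.53, adjusted p = 0.00628. Neutrophil genes had a median of 1.88 (adjusted p = 1.02e-09, or adjusted p = 0.197 with an estimated correlation), with 12 higher adjusted over the list alone. The level of this list was 13.59 ± 1.0 in HEM and 11.59 ± 0.60 in WT (SD, n = 8 and 4). At 3 months it was 12.05 ± 0.84 in HEM and 12.66 ± 0.67 in WT (SD, n = 4 and 3). The largest rises among named genes at 13 months were the eosinophil granule genes Prg2 (4.37 ± 0.83, adjusted p = 0.00314), Epx (4.31 ± 0.79, adjusted p = 0.0028) and Ear6 (4.20 ± 0.71). Ms4a3 (3.37 ± 0.79) and Ctsg (3.28 ± 0.68) of granulocyte precursors and the antibody chain Igha (3.26 ± 0.86) rose as well. With each library left out in turn, Igha ranged from 2.04 to 3.92 and lost its call in 2 of 19 fits. Of 10 monocyte genes 7 rose and 1 fell, with Ly6c2 at 1.65 ± 0.31 and Plac8 at 1.87 ± 0.41. Monocyte genes had a median of 1.39 (adjusted p = 6.35e-05, or adjusted p = 0.197 with an estimated correlation), with 8 higher and 1 lower adjusted over the list alone. Their level was lowest in WT at 13 months, at 10.61 ± 0.23 against 11.79 ± 0.54 in HEM (SD, n = 4 and 8). At 3 months it was 11.33 ± 0.50 in HEM and 11.28 ± 0.34 in WT (SD, n = 4 and 3). Of 7 tested erythroid genes 2 rose, including the red cell anion exchanger Slc4a1 (2.04 ± 0.46). Erythroid genes had a median of 1.04 (adjusted p = 6.97e-05, or adjusted p = 0.197 with an estimated correlation), with 7 higher adjusted over the list alone. WT at 13 months was the low group for the erythroid level, at 13.67 ± 0.54 against 14.97 ± 0.47 in HEM (SD, n = 4 and 8). At 3 months this level was 14.42 ± 0.82 in HEM and 14.93 ± 0.26 in WT (SD, n = 4 and 3). Of 16 T and NK cell genes 6 rose, including the cytotoxic granule genes Nkg7 (1.49 ± 0.30) and Gzma (1.39 ± 0.37). T and NK cell genes had a median of 1.25 (adjusted p = 3.65e-08, or adjusted p = 0.249 with an estimated correlation), with 16 higher adjusted over the list alone. Of 9 B cell genes 1 rose, the light chain Igkc (1.16 ± 0.32). B cell genes had a median of 0.47 (adjusted p = 0.014, or adjusted p = 0.57 with an estimated correlation), with 1 higher adjusted over the list alone. Of 20 cell cycle genes 15 rose, with the proliferation marker Mki67 at 2.12 ± 0.40, adjusted p = 0.00315 and the mitotic motor Cenpe at 1.84 ± 0.39. Cell cycle genes had a median of 1.60 (adjusted p = 8.26e-14, or adjusted p = 0.197 with an estimated correlation), with 19 higher adjusted over the list alone. With the neutrophil and erythroid marker level in the model the cell cycle median was 0.24, Mki67 0.56 and Cenpe 0.42, and the medians were 0.37 for monocyte and -0.18 for B cell genes.

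DNA methylation machinery was the exception among the remaining lists, in which few genes passed the test. Of 18 DNA methylation machinery genes 5 rose and 1 fell, with the stress-induced demethylation factor Gadd45a at 1.60 ± 0.27, adjusted p = 0.00216 and the methylcytosine oxidase Tet2 at 0.57 ± 0.10, adjusted p = 0.00225. DNA methylation genes had a median of 0.24 (adjusted p = 0.00143, or adjusted p = 0.197 with an estimated correlation), with 7 higher and 1 lower adjusted over the list alone. Here too WT at 13 months was the low group, at 11.29 ± 0.09 against 11.67 ± 0.11 in HEM (SD, n = 4 and 8). At 3 months HEM was at 11.51 ± 0.03 and WT at 11.60 ± 0.12 (SD, n = 4 and 3). None of 55 ribosomal protein genes was called. Ribosomal protein genes had a median of -0.09 (adjusted p = 0.0148, or adjusted p = 0.959 with an estimated correlation), with 0 called adjusted over the list alone. Of 22 cholesterol genes 3 fell, including Mvk (-0.37 ± 0.08) and Fdft1 (-0.31 ± 0.10, a call lost in 8 of the 19 fits that left out 1 library) of the synthesis pathway. Cholesterol genes had a median of -0.10 (adjusted p = 0.0942, or adjusted p = 0.731 with an estimated correlation), with 3 lower adjusted over the list alone. Of 20 unfolded protein and heat shock genes 1 rose, asparagine synthetase Asns (1.14 ± 0.27). Heat shock genes had a median of -0.10 (adjusted p = 0.982, or adjusted p = 0.993 with an estimated correlation), with 1 higher adjusted over the list alone. None of 19 neuron genes was called. Neuron genes had a median of 0.16 (adjusted p = 0.75, or adjusted p = 0.993 with an estimated correlation), with 0 called adjusted over the list alone. Of 14 astrocyte genes 2 fell, Clu (-0.61 ± 0.13) and Aldh1l1 (-0.43 ± 0.13, lost in 9 of those fits). Astrocyte genes had a median of -0.02 (adjusted p = 0.641, or adjusted p = 0.993 with an estimated correlation), with 2 lower adjusted over the list alone. Of 15 oligodendrocyte genes 1 fell, the chaperone Cryab (-0.79 ± 0.21). Oligodendrocyte genes had a median of 0.13 (adjusted p = 0.982, or adjusted p = 0.993 with an estimated correlation), with 1 lower adjusted over the list alone. None of 10 oligodendrocyte precursor genes and none of 14 endothelial genes was called. Oligodendrocyte precursor genes had a median of 0.12 (adjusted p = 0.982, or adjusted p = 0.993 with an estimated correlation), with 0 called adjusted over the list alone. Endothelial genes had a median of 0.25 (adjusted p = 0.29, or adjusted p = 0.993 with an estimated correlation), with 0 called adjusted over the list alone. Of 10 pericyte and smooth muscle genes 1 rose, the actin-binding Tagln (1.23 ± 0.38, lost in 6 of those fits), of whose exon bases 67.9% overlap genes on the opposite strand. Pericyte genes had a median of 0.17 (adjusted p = 0.165, or adjusted p = 0.926 with an estimated correlation), with 1 higher adjusted over the list alone. For the disease-associated microglia, Parkinson disease and heat shock lists the mean was above 0 and the median and test below, for both oligodendrocyte lists the test was below and median and mean above, and for border-associated macrophages the test was above and both below.

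The largest falls among named genes were the sulfotransferase Sult1c2 (-1.60 ± 0.46, adjusted p = 0.0293), the nuclear receptor Esrrb (-1.49 ± 0.25), the choroid plexus gene Calml4 (-1.45 ± 0.23), Otx2os1 (-1.45 ± 0.43), Prr32 (-1.45 ± 0.29), Cox8b (-1.40 ± 0.30), Grhl3 (-1.38 ± 0.25) and the insulin gene Ins2 (-1.38 ± 0.35). Otx2os1 lies antisense to Otx2, and 19.2% of its exon bases overlap genes of the other strand, so reads of the pair could be mixed. Among 739 Reactome pathways, 65 were higher and 153 lower in HEM with the preset correlation and 0 with an estimated one. The citric acid cycle and respiratory electron transport pathway led the falls, with 100 of 133 genes lower and 1 higher (median -0.52, adjusted p = 8.2e-45, adjusted p = 0.384 with an estimated correlation). Mitotic Prometaphase led the rises with 45 of 99 genes higher and 2 lower (median 0.35, adjusted p = 2.0e-12, adjusted p = 0.49 with an estimated correlation). With the neutrophil and erythroid marker level in the limma model, 0 genes passed and 1972 had an unadjusted p under 0.05, while edgeR called 2898 with TMM and 2899 with RLE factors, DESeq2 4032 and voom 3524 without it. Over the 2918 genes the median absolute log2 fold change was then 0.42, against 0.62 before, and the median SE 0.22, against 0.14. The count was 1733 without WT_13mo replicate 7, 1831 without replicate 8 and 1707 without replicate 9, and with the trend on gene length and GC content removed the split of higher and lower genes was 898 and 2280.

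**Figure D2:**
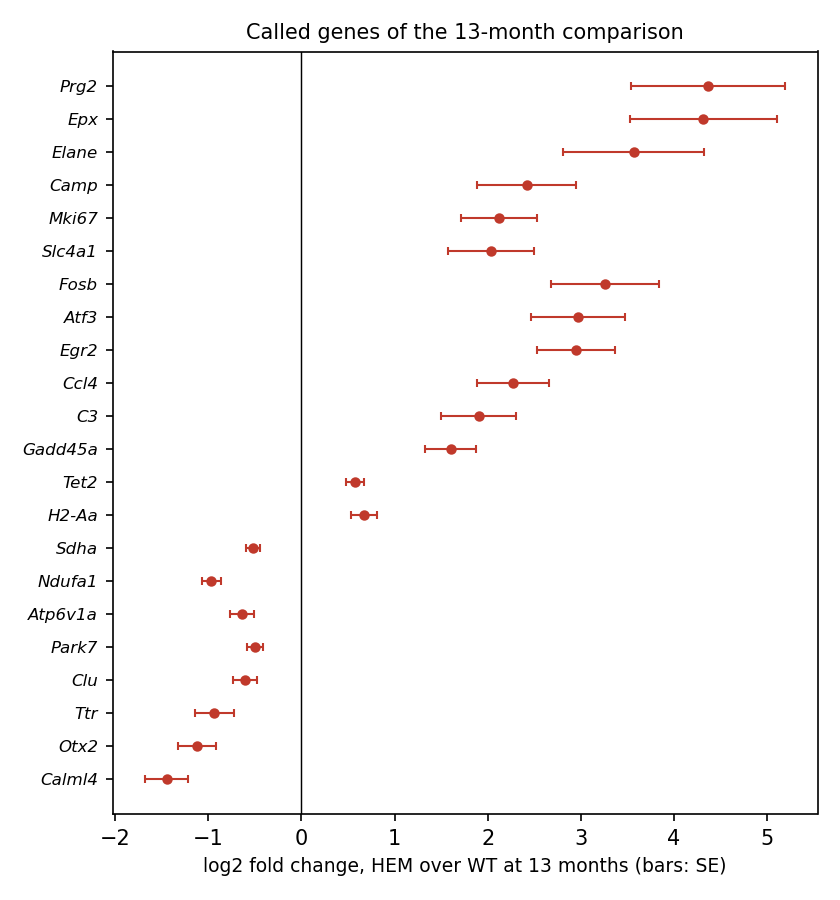
Log2 fold change of 22 named genes, HEM over WT at 13 months, from limma-trend on 8 HEM and 4 WT libraries; points are estimates and bars are standard errors. Granulocyte, cell cycle and immediate early genes lie to the right, up to 4.37 for Prg2, and mitochondrial and choroid plexus genes to the left, down to -1.45 for Calml4.

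**Figure D3:**
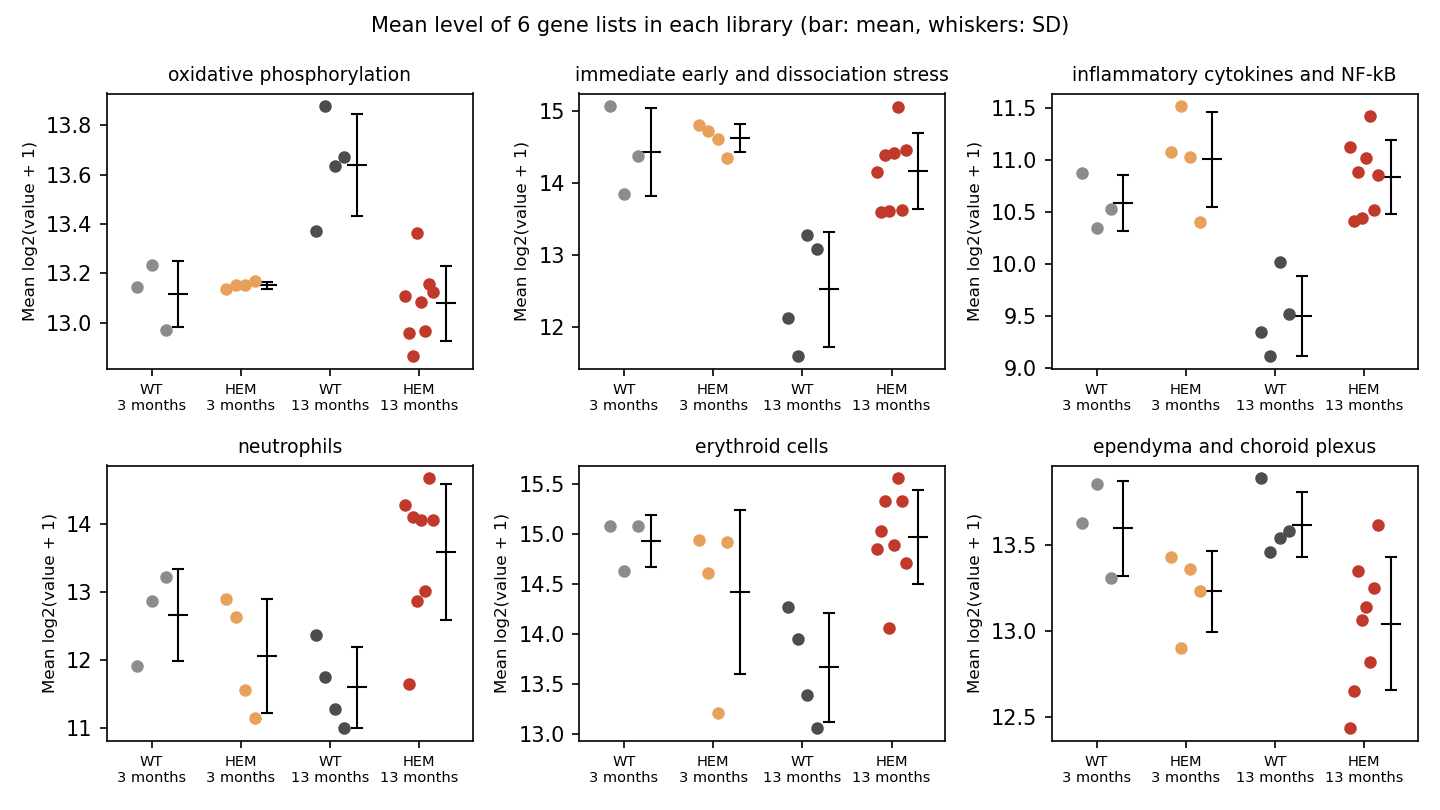
Mean log2(value + 1) of 6 gene lists in each library, by genotype and age; each point is 1 mouse, the bar is the group mean and the whiskers are the SD. The 4 WT libraries at 13 months average 13.64 for oxidative phosphorylation, against 13.08 to 13.15 in the other groups, and 12.53 for immediate early genes, against 14.17 to 14.62.

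At 3 months the same question was asked of young mice, and no gene passed the test. limma-trend called 0 genes, with 924 at an unadjusted p under 0.05 where chance gives 1199; edgeR called 0 with TMM or RLE factors, voom 0 and DESeq2 6. In simulated data for this comparison 59.7% of genes changed 2-fold and 95.5% of those changed 4-fold were called. The simulated genes were drawn independently, and the changed ones only from genes with more reads, so these shares need not hold in the data. The neuron list was the most displaced, with all 19 genes above 0 in HEM and 0 called. Neuron genes had a median of 1.10 (adjusted p = 6.84e-12, or adjusted p = 0.453 with an estimated correlation), with 0 called adjusted over the list alone. Its level was 11.84 ± 0.61 in HEM and 10.69 ± 0.73 in WT (SD, n = 4 and 3). Antigen presentation genes also lay above 0, 18 of 18, as did 22 of 24 interferon response genes and 16 of 16 T and NK cell genes. Antigen presentation genes had a median of 0.38 (adjusted p = 3.1e-10, or adjusted p = 0.341 with an estimated correlation), with 0 called adjusted over the list alone. Interferon response genes had a median of 0.26 (adjusted p = 1.69e-06, or adjusted p = 0.476 with an estimated correlation), with 0 called adjusted over the list alone. T and NK cell genes had a median of 0.65 (adjusted p = 1.71e-05, or adjusted p = 0.476 with an estimated correlation), with 0 called adjusted over the list alone. Border-associated macrophage, astrocyte and neutrophil genes lay mostly below 0. Border-associated macrophage genes had a median of -0.39 (adjusted p = 0.000423, or adjusted p = 0.453 with an estimated correlation), with 0 called adjusted over the list alone. Astrocyte genes had a median of -0.35 (adjusted p = 0.000247, or adjusted p = 0.476 with an estimated correlation), with 0 called adjusted over the list alone. Neutrophil genes had a median of -0.60 (adjusted p = 0.00149, or adjusted p = 0.65 with an estimated correlation), with 0 called adjusted over the list alone.

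Of the 29 lists at 3 months, 7 were higher and 7 lower with the preset correlation, and 0 with an estimated one. Reactome pathways gave 45 higher and 12 lower by the same preset, and 0 with an estimated one, led by Eukaryotic Translation Elongation (median 0.12, adjusted p = 0.998 with an estimated correlation) and Muscle contraction (median -0.21, adjusted p = 0.998 with an estimated correlation). The genes with the smallest p, none called by limma-trend, were the liver-type protease inhibitor Serpina1b (5.77 ± 1.40), Cpd (0.61 ± 0.15), Lgals3bp (0.50 ± 0.12) and the mitochondrial glutamate carrier Slc25a22 (0.49 ± 0.12) above 0. Below 0 they were Bloc1s1 (-1.08 ± 0.30), Morn3 (-1.07 ± 0.30), Id4 (-0.86 ± 0.24) and Fgf11 (-0.66 ± 0.19). The limma adjusted p was 1.0 for each, while DESeq2 called Serpina1b (adjusted p = 2.67e-05). Serpina1b belongs to a cluster of near-identical genes whose reads could be divided among them, and 55.9% of the exon bases of Bloc1s1 overlap Rdh5 on the same strand.

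In WT mice, the age comparison asked what differed between 13 and 3 months without the transgene. In both genotypes the 2 ages were different mice, and age may go with a processing batch, which the labels do not give. A change with age below can therefore not be told apart from a difference between cohorts or in handling. Some respiratory chain genes were higher and some immediate early and smooth muscle genes lower at 13 months. Mitochondrial transcripts made up 3.51 to 4.62% of the reads per library in WT at 3 months and 6.96 to 10.9% at 13 months, and 3.78 to 5.52% and 3.68 to 13.4% in HEM. Of 34 oxidative phosphorylation genes 8 rose, including the complex I subunit Ndufs3 (0.55 ± 0.10, adjusted p = 0.0252) and the complex III hinge protein Uqcrh (0.65 ± 0.13, adjusted p = 0.0336). Oxidative phosphorylation genes had a median of 0.53 (adjusted p = 5.34e-32, or adjusted p = 0.179 with an estimated correlation), with 34 higher adjusted over the list alone. Of 20 immediate early genes 9 fell. Immediate early genes had a median of -1.74 (adjusted p = 7.59e-23, or adjusted p = 0.179 with an estimated correlation), with 18 lower adjusted over the list alone. Fosb fell from 48146 ± 15368 to 7583 ± 8212 normalized counts (SD, n = 3 and 4; -3.52 ± 0.72, adjusted p = 0.0341), with Atf3 (-2.98 ± 0.62), Egr2 (-2.72 ± 0.52), Fos (-2.33 ± 0.47) and Klf4 (-1.57 ± 0.28). Of 24 inflammatory genes 1 fell, Il10 (-3.47 ± 0.73). Inflammatory genes had a median of -1.18 (adjusted p = 9.71e-11, or adjusted p = 0.235 with an estimated correlation), with 10 lower adjusted over the list alone. Of 10 pericyte and smooth muscle genes 3 fell, among them the smooth muscle actin Acta2 (-2.93 ± 0.58, adjusted p = 0.0305) and myosin Myh11 (-2.77 ± 0.48, adjusted p = 0.0218). Pericyte genes had a median of -0.51 (adjusted p = 0.000276, or adjusted p = 0.491 with an estimated correlation), with 3 lower adjusted over the list alone. The receptor genes Olfr558 (-2.74 ± 0.43) and Gpr20 (-2.33 ± 0.40) fell as well. Of 14 endothelial genes 0 were called, although all 14 lay below 0. Endothelial genes had a median of -1.03 (adjusted p = 2.06e-08, or adjusted p = 0.426 with an estimated correlation), with 8 lower adjusted over the list alone.

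Of the named genes Serpina1b rose most with age in WT, from 3.8 ± 2.3 to 1209.6 ± 451 normalized counts (SD, n = 3 and 4; 8.02 ± 1.40, adjusted p = 0.0218), followed by Sult1c2 (3.84 ± 0.58, adjusted p = 0.0208), the homeobox gene Tlx2 (3.30 ± 0.53, adjusted p = 0.0208), Bhmt2 (1.71 ± 0.38), Tc2n (1.68 ± 0.29), the circadian regulator Per2 (1.55 ± 0.34) and Prom2 (1.42 ± 0.30). Serpina1b also varied widely among HEM mice of the same age, from 7.67 to 938 at 3 months and from 22.4 to 2081 at 13 months. Of 18 antigen presentation genes 2 rose, H2-DMb1 (1.41 ± 0.24, adjusted p = 0.0218) and H2-K1 (1.20 ± 0.22, adjusted p = 0.0243). Antigen presentation genes had a median of 0.07 (adjusted p = 0.0392, or adjusted p = 0.58 with an estimated correlation), with 3 higher adjusted over the list alone. Of 55 ribosomal protein genes 1 rose, Rps18 (1.30 ± 0.24, adjusted p = 0.0224), which lies beside H2-K1 on chromosome 17. Ribosomal protein genes had a median of 0.27 (adjusted p = 4.98e-12, or adjusted p = 0.491 with an estimated correlation), with 11 higher adjusted over the list alone. The astrocyte enzyme Aldh1l1 (0.71 ± 0.16) was the 1 riser of 14 astrocyte genes. Its call was lost in 15 of the 19 fits that left out 1 library, and its lowest change over all alternatives was 0.24. Astrocyte genes had a median of 0.31 (adjusted p = 0.00466, or adjusted p = 0.491 with an estimated correlation), with 3 higher adjusted over the list alone. Gadd45b (-1.77 ± 0.38) was the 1 faller of 18 DNA methylation machinery genes. DNA methylation genes had a median of -0.16 (adjusted p = 0.00466, or adjusted p = 0.334 with an estimated correlation), with 1 higher and 5 lower adjusted over the list alone. Erythroid and neutrophil genes lay below 0 in 7 of 7 and 12 of 12 genes, with 0 called. Erythroid genes had a median of -1.17 (adjusted p = 3.82e-05, or adjusted p = 0.319 with an estimated correlation), with 4 lower adjusted over the list alone. Neutrophil genes had a median of -1.02 (adjusted p = 0.000313, or adjusted p = 0.491 with an estimated correlation), with 0 called adjusted over the list alone.

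In all, 170 genes changed with age in WT by limma-trend, 111 higher and 59 lower at 13 months, with 3714 at an unadjusted p under 0.05; edgeR called 103 with TMM and 93 with RLE factors, DESeq2 1217 and voom 1255. Over all tested genes the 2 groups did not overlap for 15.3%, which chance gives for 5.71%. Reactome pathways gave 147 higher and 38 lower with the preset correlation and 0 with an estimated one. Respiratory electron transport with ATP synthesis led, with 17 of 97 genes higher (median 0.52, adjusted p = 0.513 with an estimated correlation). The count depended on single libraries in both ages, and 0 of 24 named calls held in each of the 19 fits that left out 1 library. It was 0 without WT_13mo replicate 7, 102 without replicate 8, 4 without replicate 9 and 523 without replicate 6, 0, 1 and 0 without WT_3mo replicates 1, 3 and 5, 80 and 102 without HEM_3mo replicates 1 and 4, and 468 without HEM_13mo replicate 7. With the neutrophil and erythroid marker level in the model limma called 0, although the 170 genes kept their direction and a median absolute log2 fold change of 0.89, against 0.93 before, while the median SE rose from 0.19 to 0.23.

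In HEM mice, the same age comparison showed more transcript of some astrocyte genes and of genes such as Epx and Jchain at 13 months, and less of the endothelial genes Kdr and Cdh5. Epx, the eosinophil peroxidase, rose from 166 ± 88.8 to 2649.8 ± 2413 normalized counts (SD, n = 4 and 8; 3.68 ± 0.79, adjusted p = 0.0252), and Ear6 by 2.91 ± 0.71. The call of Ear6 was lost in 13 of the 19 fits that left out 1 library, and that of Epx in 3. Jchain, which joins secreted antibodies, rose by 3.21 ± 0.46 (adjusted p = 0.0046), and Igkc, the 1 riser of 9 B cell genes, by 1.61 ± 0.32. B cell genes had a median of 0.45 (adjusted p = 0.00217, or adjusted p = 0.699 with an estimated correlation), with 1 higher adjusted over the list alone. The platelet chemokine Ppbp (2.67 ± 0.56), the red cell genes Car1 (2.65 ± 0.65) and Kel (2.64 ± 0.65), and Rab44 (2.36 ± 0.45) rose too, as did Slc4a1 (2.03 ± 0.46), the 1 riser of 7 erythroid genes. The calls of Car1 and Kel were lost in 15 and 14 of the 19 fits that left out 1 library, and that of Slc4a1 in 6. Over all alternatives the lowest change was 1.26 for Car1 and 1.19 for Kel. Erythroid genes had a median of 0.08 (adjusted p = 0.139, or adjusted p = 0.795 with an estimated correlation), with 2 higher adjusted over the list alone. Neutrophil genes lay above 0 in 12 of 12, with 0 called. Neutrophil genes had a median of 1.54 (adjusted p = 2.96e-09, or adjusted p = 0.47 with an estimated correlation), with 12 higher adjusted over the list alone. Their level was 13.59 ± 1.0 at 13 months and 12.05 ± 0.84 at 3 months (SD, n = 8 and 4). All 20 cell cycle genes also lay above 0, with 0 called. Cell cycle genes had a median of 0.76 (adjusted p = 1.77e-07, or adjusted p = 0.699 with an estimated correlation), with 3 higher adjusted over the list alone, and the median was -0.061 with the neutrophil and erythroid marker level in the model. Of 34 oxidative phosphorylation genes and 24 interferon response genes 0 were called. Oxidative phosphorylation genes had a median of -0.08 (adjusted p = 0.0259, or adjusted p = 0.801 with an estimated correlation), with 0 called adjusted over the list alone. Interferon response genes had a median of -0.25 (adjusted p = 0.0124, or adjusted p = 0.795 with an estimated correlation), with 0 called adjusted over the list alone.

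Of 14 astrocyte genes 6 rose and 1 fell with age in HEM, including the glutamate transporters Slc1a2 (1.42 ± 0.26, adjusted p = 0.0162) and Slc1a3 (1.38 ± 0.25, adjusted p = 0.0162). Astrocyte genes had a median of 0.50 (adjusted p = 2.27e-07, or adjusted p = 0.47 with an estimated correlation), with 10 higher and 1 lower adjusted over the list alone. Ptprz1 was the 1 riser of 10 oligodendrocyte precursor genes (1.12 ± 0.21). Oligodendrocyte precursor genes had a median of -0.40 (adjusted p = 0.465, or adjusted p = 0.801 with an estimated correlation), with 1 higher adjusted over the list alone. Of 14 endothelial genes 2 fell, the VEGF receptor Kdr (-1.44 ± 0.31, adjusted p = 0.0247) and the junction cadherin Cdh5 (-1.18 ± 0.25, adjusted p = 0.0242). Endothelial genes had a median of -0.95 (adjusted p = 2.96e-09, or adjusted p = 0.47 with an estimated correlation), with 12 lower adjusted over the list alone. Other falls were the chemokine receptor Ccr6 (-3.85 ± 0.89, adjusted p = 0.0341), the potassium channel Kcnq1 (-1.97 ± 0.33), Pcdh12 (-1.93 ± 0.40), Syt6 (-1.79 ± 0.38), the opioid precursor Penk (-1.71 ± 0.30), Olfr558 (-1.69 ± 0.35), Cpz (-1.67 ± 0.28) and the arterial gene Gkn3 (-1.66 ± 0.41). The call of Gkn3 was lost in 15 of the 19 fits that left out 1 library, while that of Cpz held in each. Of 27 lysosome genes 3 fell, among them the acid glucosidase Gaa (-0.52 ± 0.11) and Smpd1 (-0.40 ± 0.09). Lysosome genes had a median of -0.17 (adjusted p = 8.08e-06, or adjusted p = 0.47 with an estimated correlation), with 1 higher and 9 lower adjusted over the list alone. The water channel Aqp1 (-0.72 ± 0.17) was the 1 faller of 12 ependyma and choroid plexus genes, and the lipoprotein receptor Scarb1 (-0.67 ± 0.15) the 1 faller of 22 pattern recognition genes. Choroid plexus genes had a median of -0.23 (adjusted p = 0.0216, or adjusted p = 0.699 with an estimated correlation), with 3 lower adjusted over the list alone. Pattern recognition genes had a median of -0.01 (adjusted p = 0.499, or adjusted p = 0.801 with an estimated correlation), with 1 higher and 1 lower adjusted over the list alone. Neuron genes lay below 0 in 19 of 19, with 0 called. Neuron genes had a median of -0.94 (adjusted p = 2.92e-06, or adjusted p = 0.699 with an estimated correlation), with 0 called adjusted over the list alone.

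Genes of the H2 complex on chromosome 17 rose with age in HEM as well. Of 18 antigen presentation genes 4 rose, with H2-K1 (mm10 33996017 to 34000347) at 1.05 ± 0.18, adjusted p = 0.0116 and H2-DMb1 at 1.05 ± 0.19, adjusted p = 0.0162. Antigen presentation genes had a median of 0.15 (adjusted p = 0.0124, or adjusted p = 0.795 with an estimated correlation), with 6 higher and 1 lower adjusted over the list alone. Rps18 beside them rose by 1.54 ± 0.19 (adjusted p = 0.00292), the 1 riser of 55 ribosomal protein genes, and Sult1c2 by 2.12 ± 0.46. Ribosomal protein genes had a median of 0.06 (adjusted p = 0.139, or adjusted p = 0.801 with an estimated correlation), with 1 higher adjusted over the list alone. In all, 388 genes changed by limma-trend, 224 higher and 164 lower at 13 months, with 3974 at an unadjusted p under 0.05; edgeR called 372 with TMM and 368 with RLE factors, DESeq2 1308 and voom 1466. Over all tested genes the groups did not overlap for 2.79%, which chance gives for 0.404%. Reactome pathways gave 39 higher and 78 lower, and 0 with an estimated correlation, led by Mitotic Prometaphase (median 0.27, adjusted p = 0.991 with an estimated correlation) and Elastic fibre formation (median -0.39, adjusted p = 0.181 with an estimated correlation). With the neutrophil and erythroid marker level in the model the count was 1, although the 388 genes kept their direction and a median absolute log2 fold change of 0.82, against 0.90 before, while the median SE rose from 0.19 to 0.24. It was 648, 243 and 209 without HEM_13mo replicates 3, 12 and 13, and 62, 118 and 163 without HEM_3mo replicates 1, 4 and 7.

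**Figure D4:**
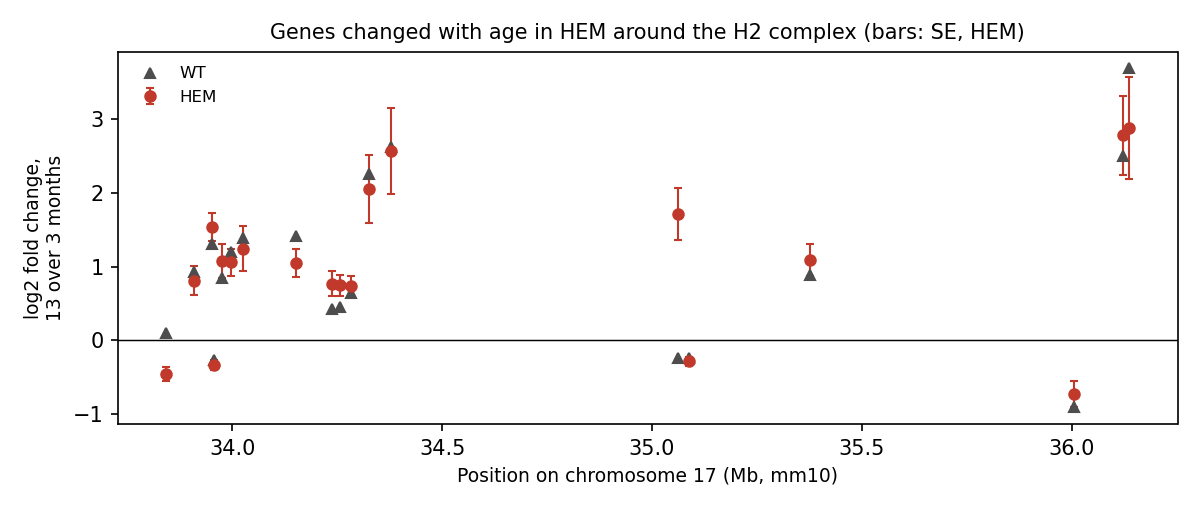
Log2 fold change with age of the 19 genes on chromosome 17 from 33000000 to 37000000 (mm10) that changed between 13 and 3 months in HEM, plotted by position; circles with standard error bars are HEM and triangles are WT. Of the 19 genes, 17 had the same direction in WT.

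Genes called with age in both genotypes numbered 13 in the rising direction, where independent lists would share 1.04, and 6 in the falling direction, where they would share 0.404. None moved in opposite directions (1.31 by independence). Rps18, H2-K1, H2-DMb1, Sult1c2 and Olfr558 were among the shared genes. Across genes, which are not independent replicates, the age effects in WT and HEM correlated at r = 0.091, and the genotype effects at 13 and 3 months at r = -0.027.

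Whether the genotype effect differed between 13 and 3 months was tested directly. No single gene passed the test, with 0 called by limma-trend at a lowest adjusted p of 0.0742 and 3551 genes at an unadjusted p under 0.05; edgeR called 0 with TMM or RLE factors, voom 794 and DESeq2 938. As lists, oxidative phosphorylation genes had lower genotype effects at 13 months in 34 of 34. Oxidative phosphorylation genes had a median of -0.58 (adjusted p = 1.54e-28, or adjusted p = 0.246 with an estimated correlation), with 31 lower adjusted over the list alone. Neutrophil genes had higher ones in 12 of 12, cell cycle genes in 20 of 20 and immediate early genes in 18 of 20. Neutrophil genes had a median of 2.50 (adjusted p = 1.28e-11, or adjusted p = 0.289 with an estimated correlation), with 12 higher adjusted over the list alone. Cell cycle genes had a median of 1.51 (adjusted p = 4.92e-10, or adjusted p = 0.343 with an estimated correlation), with 14 higher adjusted over the list alone, and the median was -0.22 with the neutrophil and erythroid marker level in the model. Immediate early genes had a median of 1.52 (adjusted p = 9.59e-12, or adjusted p = 0.289 with an estimated correlation), with 17 higher adjusted over the list alone. Of the 29 lists, 10 were higher and 5 lower with the preset correlation, and 0 with an estimated one. Reactome pathways gave 46 higher and 141 lower with the preset, and 0 with an estimated one. The smallest p belonged to Epx (6.87 ± 1.27), Ear6 (5.86 ± 1.14), Ppp1r12a (0.75 ± 0.13) and Pcf11 (0.59 ± 0.11) above 0. Below 0 they belonged to the methyltransferase Gnmt (-1.53 ± 0.26), Pebp1 (-1.10 ± 0.20), Lgals3bp (-0.90 ± 0.15) and Asna1 (-0.73 ± 0.13), all at a limma adjusted p of 0.0742. DESeq2 and voom called each of these 8. Thy1 differed by -0.70 ± 0.79 (adjusted p = 0.753). The count was 313 without HEM_13mo replicate 7, 280 without WT_13mo replicate 6, 4 without WT_3mo replicate 1, 2 without HEM_13mo replicate 1 or HEM_3mo replicate 4, and 1 without WT_13mo replicate 9 or HEM_3mo replicate 3.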

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

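The fits with thinned reads, with the length and GC trend removed and with the neutrophil and erythroid marker level were added after the data were seen. The tests of that marker level on list levels were written once its effect on the gene count was known, before the level differences were seen.

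At 13 months HEM differed from WT in 2918 genes. Of 100 splits of the 12 libraries, drawn from 495, the real one was the 1 that called as many (highest other 105). A share of 1 in 100 is the smallest these splits can give, so chance is unlikely by this test but not excluded. Splits of the mice cannot tell genotype from a day, litter or batch that the labels do not give. The tables argue against depth and gene composition as the whole cause: with each library thinned to 60 M reads, 95.3% of the genes were still called (2925 in all), and with the trend on gene length and GC content removed the difference in the oxidative phosphorylation level was -0.67 ± 0.10 (SE), against -0.56 ± 0.09 before. They also argue against RNA that follows the neutrophil and erythroid marker level as the whole cause for 2 lists. With that level in the model the oxidative phosphorylation difference was -0.44 ± 0.14. The immediate early difference was 1.71 ± 0.56, against 1.64 ± 0.34 before. That level does not follow all blood cells, since the median of T and NK cell genes was 1.51 with it and 1.25 before. RNA of other blood cells therefore stays open for the 2 lists. For cell cycle, monocyte and interferon genes most of the change went with that level. Their medians fell from 1.60 to 0.24, from 1.39 to 0.37 and from 0.52 to 0.20, so blood or marrow RNA stays open for these. That limma model nevertheless called 0 genes (lowest adjusted p 0.254, 1972 at an unadjusted p under 0.05), because over the 2918 genes the median absolute log2 fold change was 0.42 in place of 0.62 and the median SE 0.22 in place of 0.14, so for single genes blood or marrow RNA stays open, as does the effect of genotype. Stress of tissue handling could link the lists, yet within groups the immediate early and oxidative phosphorylation levels correlated at r = -0.34 (rho = -0.30, permutation p = 0.287 and 0.299, adjusted p = 0.287 over 9 relations, r = -0.11 without the 2 farthest libraries), too few libraries to decide, and the labels give no day, litter or batch.

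For the other comparisons, the 388 genes of the HEM age comparison were the most of 100 splits, with 1 as large and the highest other at 236. By the share of splits chance is therefore unlikely. The count was 62, 118 and 163 without HEM_3mo replicates 1, 4 and 7, each below that 236. The 170 of the WT age comparison were the most of 35 splits of its 7 libraries, with 1 as large. A share of 1 in 35 is the smallest these splits can give, so chance is unlikely by this test but not excluded. The margin was narrow, with the highest other at 159. The count was 0 and 4 without WT_13mo replicates 7 and 9 and 0, 1 and 0 without WT_3mo replicates 1, 3 and 5. At 3 months and for the difference of the genotype effects the real count was 0. As any split gives at least 0 genes, the 35 of 35 splits (highest other 1) and the 100 of 100 reassignments of genotype within age (highest other 0) decide nothing there.

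A library far from the rest of its group was found in 13 of 301 groups of values, and chance gives 15.05. Values are the gap to the nearest library as a share of the group's range. HEM_13mo replicate 7 was highest for Calml4 (0.538), Sdha (0.596) and Asna1 (0.718). HEM_13mo replicate 4 was lowest for Slc2a5 (0.56) and Pcdh12 (0.667), replicate 3 lowest for Cryab (0.585), replicate 8 highest for Tagln (0.659) and replicate 1 highest for the Parkinson disease list (0.533). HEM_3mo replicate 4 was lowest for Bloc1s1 (0.963) and Serpina1b (0.851). WT_13mo replicate 9 was lowest for Gzma (0.851) and highest for Sult1c2 (0.931), and WT_13mo replicate 7 was highest for H2-Aa (0.866).

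For 15 lists the genotype effect differed between 13 and 3 months by camera with the preset correlation, and for 0 with an estimated one. The median difference, 13 minus 3 months, was 2.50 for neutrophils, 1.42 for erythroid cells and 1.52 for immediate early genes (adjusted p = 0.289 for each with an estimated correlation). It was 1.51 for cell cycle, 1.25 for monocytes, 0.95 for B cells, 0.56 for inflammatory and -0.21 for lysosome genes (adjusted p = 0.343 for each with an estimated correlation). With the neutrophil and erythroid marker level in the model it was -0.22 for cell cycle and -0.063 for monocytes. Oxidative phosphorylation differed by -0.58 and DNA methylation machinery by 0.38 (adjusted p = 0.246 for both with an estimated correlation). Neurons differed by -1.03 and ribosomal proteins by -0.21 (adjusted p = 0.656 for both with an estimated correlation). Ependyma and choroid plexus differed by -1.06, pericytes and smooth muscle by 0.62, and T and NK cells by 0.70 (adjusted p = 0.352, 0.564 and 0.763 with an estimated correlation). With the animal number as a block the T and NK cell median was -0.79, called lower by camera with the preset correlation (adjusted p = 0.0017). The limits of that block model are given below.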

How the results depend on the processing

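The alternatives added after the data were seen began with both pseudocounts, TMM scaling and the neutrophil and erythroid covariate. The rest were thinning, the length and GC trend, and leaving out 3 libraries apart on principal components. TMM scaling kept direction and call for 208 of 209 results, thinning for 207 and the length and GC trend for 200. The planned edgeR test with TMM factors kept 116 of 132, with 16 weaker. The estimated correlation ended the call of 77 of 77 list results. The neutrophil and erythroid covariate kept 65 of 209, weakened 132 and reversed 12. The cause was not tested except where stated.

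With that covariate 0 genes were called at 13 months (1972 at an unadjusted p under 0.05), 0 in the WT age comparison and 1 in the HEM age comparison. The folds of the age genes stayed about as large, with medians of 0.89 against 0.93 before in WT and 0.82 against 0.90 in HEM and each gene in the same direction, while the median SE rose from 0.19 to 0.23 and from 0.19 to 0.24. At 13 months the median fold was 0.42 against 0.62 and the median SE 0.22 against 0.14. Ms4a3 at 13 months reversed to -0.087. Named genes that kept under 50% of their 13-month change were Camp (0.027), C3 (0.22), Slc4a1 (0.23), Ctsg (0.34), Plac8 (0.38), Cenpe (0.42), Elane (0.42), Gzma (0.47), Asns (0.49), Ly6c2 (0.54), Mki67 (0.56), Igkc (0.58), Gadd45a (0.69), Sparc (-0.12) and Timp2 (-0.16), of which Camp, Elane and Slc4a1 are part of the covariate. So did the lists cell cycle (median 0.24), monocytes (0.37), interferon response (0.20), lysosome (-0.065) and erythroid cells (0.18, part of the covariate). Lists whose test reversed had medians of -0.0052 (ribosomal proteins), -0.18 (B cells) and -0.23 (neutrophils) at 13 months, 0.20 (neutrophils) at 3 months, 0.21 (cell cycle) and 0.49 (neutrophils) for WT age, 0.0043 (oxidative phosphorylation) and -0.061 (cell cycle) for HEM age, and -0.22 (cell cycle), -0.32 (neutrophils) and -0.063 (monocytes) for the difference of the genotype effects. The neutrophil genes are part of the covariate, so the 4 reversals of that list follow from the model and say nothing about it.

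Nothing in the labels says that animal numbers pair the samples, and the values are too few to settle it. Between same-numbered libraries, deviations from group means correlated at r = 0.107 and 0.126 at 13 months and 0.021 and -0.038 at 3 months. Across ages in HEM r was -0.068, 0.022, 0.114 and 0.173. Among the libraries of the other group the same-numbered one ranked 1 and 2 at 13 months and 2 and 3 at 3 months. Across ages in HEM it ranked 3, 1, 1 and 1. A block on the number in effect leaves out each library whose number occurs once. At 13 months only numbers 7 and 8 occur in both genotypes. The 2 WT groups share no number, so with the block the WT age effect is linked only through HEM libraries. A lost or reversed result under the block can therefore come from the model alone. With the number as a block, 0 genes were called at 13 months (2717 at an unadjusted p under 0.05), 0 for WT age and 1 for HEM age. The folds of the called genes had medians of 0.52 against 0.62 before at 13 months, 0.72 against 0.93 for WT age and 0.90 against 0.90 for HEM age, and the median SE was 0.19, 0.26 and 0.23 in place of 0.14, 0.19 and 0.19. Named genes that kept under 50% of their 13-month change were Ms4a6b (0.056), Aldh1l1 (-0.13), Asns (0.50) and Gzma (0.57), and lists T and NK cells (median 0.35, against 1.25), pattern recognition (0.094), monocytes (0.69) and B cells (-0.13). With the block, Thy1 reversed to 0.30 for WT age, as did the test of the lists pattern recognition (median 0.14), astrocytes (-0.0063) and B cells (0.53). For the difference of the genotype effects the T and NK cell list reversed to a call the other way (median -0.79, camera adjusted p = 0.0017 with the preset correlation). The test of ependyma reversed too, while its median stayed below 0 (-0.25, against -1.06 without the block).

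For WT age the count was 79 with no filter, 292 with the filter at 50, 77 with the 2 groups alone, 103 and 93 with edgeR (TMM and RLE factors), 1255 with voom, 1217 with DESeq2 and 256 without the 3 libraries. For HEM age it was 725 with the neural covariate, 231 with the 2 groups alone, 1466 with voom, 1308 with DESeq2 and 203 without the 3 libraries. For the difference of the genotype effects it was 794 with voom, 938 with DESeq2 and 1 without the 3 libraries. DESeq2 called 6 genes at 3 months. Interferon genes for HEM age reversed to 0.0059 without the 3 libraries.

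Leaving out each library in turn gave 1707 to 3287 genes at 13 months, 0 to 0 at 3 months, 0 to 523 for WT age, 62 to 648 for HEM age and 0 to 313 for the difference of the genotype effects. Of the named calls, 41 of 57 at 13 months, 0 of 24 for WT age and 7 of 30 for HEM age (Cpz, H2-DMb1, H2-K1, Jchain, Kcnq1, Penk and Rps18) held in each of the 19 fits. At 13 months the calls lost, with the number of fits, were Slc2a5 (14), Sparc (12), Aldh1l1 (9), Fdft1 (8), Ms4a6b (7), Tagln (6), Otx2os1 (5), Igkc (4), Sult1c2 and Timp2 (3 each), Cryab and Igha (2 each), and Asns, Gzma, Ms4a3 and Zbp1 (1 each). Depth did not limit the 13-month count, since thinning to 60 M reads gave 2925.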

Other observations

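All tests in this part were chosen after the data were seen.

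Markers of cells outside the fixed lists were also present. Granulocyte precursors of the marrow stood out: Mpo, Prtn3 and Fcnb rose, 3 of 3 (median 3.07), and Mpo averaged 15858 ± 13874 normalized counts in HEM and 1275 ± 593 in WT at 13 months (SD, n = 8 and 4). In the first version of that list 6 of 6 rose (median 3.25). Of 7 circulating neutrophil genes 5 rose (median 1.62). The precursor level moved 1.66 ± 0.45 (SE) further than the circulating level on the log2 scale, or 1.81 ± 0.46 with the first list. Of 4 tested osteoblast genes 0 were called (median 0.41), and 1 of 5 in the first version (0.77). The tested members did not share 1 pattern over the groups. Dmp1 averaged 1349 in HEM and 1493 in WT at 13 months, against 655 and 778 at 3 months. Sp7 averaged 157 to 178 in the 4 groups. Bglap averaged 61.1 in HEM at 13 months, with 1 maximum of 426. Their mean, the osteoblast level, therefore need not be that of 1 cell type. Over the 19 libraries the osteoblast level correlated with the precursor level at r = 0.62 (rho = 0.63, permutation p = 0.00379 and 0.00462, adjusted p = 0.00853 over 9 relations, r = 0.42 without the 2 farthest). Within groups r was 0.56 (rho = 0.51, permutation p = 0.0309 and 0.0539, adjusted p = 0.0464, r = 0.41 without the 2 farthest). The first lists gave r = 0.77 (rho = 0.78, permutation p = 1e-04 and 0.00021, adjusted p = 0.00045, r = 0.64 without the 2 farthest) and, within groups, r = 0.67 (rho = 0.65, permutation p = 0.0076 and 0.01, adjusted p = 0.0137, r = 0.56 without the 2 farthest). Of 7 anterior pituitary genes 0 were called (median -2.48), with growth hormone, Gh, between 23.4 and 114175 normalized counts across libraries.

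Genes that changed with age in HEM were dense around the H2 complex, on chromosome 17 from 33000000 to 37000000, where 19 of 211 tested genes changed against 3.42 by chance. Leaving out the named genes, 14 changed against 3.02 by chance, 10 higher and 4 lower (permutation p = 1e-05 over genes, the lowest possible). The permutations in this paragraph draw genes as if independent and do not reassign mice. They therefore do not exclude a chance difference between the mice of the age cohorts. Parental haplotypes, C57BL/6 and DBA/2, that differ between the age cohorts could give such a density, but no genotypes were tested. In WT 0 changed besides the named genes, against 1.23 by chance, and 3 with them, against 1.5 (permutation p = 0.188), too few to decide there. Of the 19 genes 17 had the same direction in WT, and 4 did not overlap between the ages. A change of MHC expression with age stays open, as do reads divided between similar H2 genes.

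The densest window for the WT age comparison lay elsewhere, on chromosome 12 from 100000000, where 7 of 57 genes changed (adjusted p = 0.000106 over 678 windows). They were Tc2n, Gm8893 and Serpina1a, Serpina1b, Serpina1c, Serpina1d and Serpina1e, a cluster of liver-type protease inhibitors with near-identical sequence. Serpina1b lay between 1.86 and 6.34 normalized counts in WT at 3 months and between 808 and 1852 in WT at 13 months. In HEM it ranged from 7.67 to 938 at 3 months and from 22.4 to 2081 at 13 months. The densest window for HEM age was on chromosome 17 from 32000000, with 18 of 204 genes (adjusted p = 4.63e-06). The adjusted p of both windows likewise treat neighbouring genes as independent and do not measure chance between mice. At 13 months the H2 region held 16 genes that differed between HEM and WT, against 25.7 by chance.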
